A study of Mus musculus with 7 samples.

How the data were processed

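Total RNA from 7 mouse T cell samples was labelled with Cy3 and hybridized to Agilent 1-colour microRNA arrays, 1 array per sample. The scanner files hold 11540 spots per array, for 1712 probes and 576 microRNAs, with 953 control spots. Per the file headers, their spot signals are fluorescence intensity values that Agilent Feature Extraction had background-subtracted and not scaled between arrays, with version 10.1.1.1 for the 3 unsorted arrays and version 10.7.3.1 for the 4 sorted arrays. The authors' processed table gives log2 values for 197 microRNAs, with undetected microRNAs listed at 0. Its columns share most of their values above 0 (89.7% to 99.4% between any 2 columns) and all of those at ranks 2 to 6, as after a quantile normalization, but the highest value is 13.10 in the sorted and 12.55 in the unsorted columns, so the exact step is not known. For that table the submitters name limma without a version or steps.

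Values were computed from the scanner files, each taken under the sample it was deposited for. Spots of a probe were averaged on the linear scale after division by the array's 75th percentile, taken over the 94 probes detected on all arrays. A floor of 0.0964 (-3.38 on the log2 scale) was then applied, the highest over the arrays of the lowest scaled signal well above background, and the brightest probe stood for each microRNA. A probe counted as detected when at least 0.5 of its spots were well above background. Tested were the microRNAs detected on every array of at least 1 group (146 microRNAs). No spot was saturated (0 on each array). Signal over background differed between batches: 20.6% to 25.0% of spots were well above background on the sorted arrays and 9.12% to 12.0% on the unsorted ones. Pearson correlations across the 54 microRNAs detected on all arrays were 0.973 to 0.990 between sorted arrays, 0.767 to 0.863 between unsorted arrays and 0.555 to 0.723 between the batches. The microRNAs are not independent replicates.

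Samples fell into 4 groups: antigen-driven Th17 culture (n = 1), sorted antigen-driven Th17 cells (n = 4), activated CD4+ T cells (n = 1) and polyclonal Th17 culture (n = 1). The sorted cells were compared with each other group by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, 1 mean per group), two-sided, with a Benjamini-Hochberg adjusted p threshold of 0.05. The files were read with the data.table package, version 1.17.8. The spread came from the 4 sorted arrays alone (3 residual degrees of freedom). In the main analysis, comparisons of 1 array with 1 had no test and count microRNAs at least 2-fold apart. Gene lists (24, of which 18 had 2 or more tested members), tests, groups and most alternatives were fixed before the data were examined. Lists in the sorted contrasts were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry. In the others, the median over a list's tested members, detected or not, was placed among 10000 random lists. Those lists had the same size and were matched on mean signal. The resulting percentiles were not adjusted over the 18 lists. Random lists treat microRNAs as separate, while cluster lists hold neighbouring genes that may differ together.

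The named microRNAs are, per contrast, the 10 largest increases and 10 largest decreases among those called and detected on both sides, the same way on all 4 sorted arrays, or at least 2-fold apart between single arrays. Added to these are members of the lists and at most 5 per direction detected on 1 side only, whose folds against the floor are lower bounds. MicroRNAs in the count against all 3 unsorted arrays were named after their values were seen.

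The fit was tested in 50 simulations with 30 changed microRNAs, where every array had the spread of the sorted arrays and no batch difference. Over all tested microRNAs it recovered 76.9% of 2-fold and 87.3% of 4-fold changes, with 16.6% false calls, because many microRNAs have no spread at the floor. Among microRNAs above the floor it recovered 83.2% and 95.7% with 3.48% false calls, so counts above the floor are given beside the others.

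Alternatives were quantile normalization, the software's sum per microRNA, the mean of all probes, no floor, stricter detection, normexp background correction with an offset of 50, a fold threshold of 1.5, the authors' values, limma's test of single arrays with the spread of the sorted arrays, the 5 antigen-driven arrays as 1 group, and leaving out each sorted array. Re-centring the background, testing above the floor, the count against all 3 unsorted arrays and the Sfmbt2 list without miR-574-5p were chosen after seeing the data. The planned normexp input was absent, and the median signal took its place. Distances between microRNA genes used a mouse gene annotation whose build the array files do not name, so no positions are printed.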

Results

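MicroRNA levels were measured in mouse T helper 17 (Th17) cells and in activated CD4+ T cells on 7 Agilent microRNA arrays, each hybridized with Cy3-labelled total RNA. Th17 cells are the helper T cells that make interleukin 17. Cells were grown from naive CD4+ T cells of the spleen and the lymph nodes of the gut, and TGFbeta and IL-6 were the polarizing cytokines. The antigen-driven Th17 cultures received ovalbumin and came from OTII BALB/c mice, whose transgenic T cell receptor recognizes it. The groups were 1 antigen-driven Th17 culture, 4 arrays of sorted antigen-driven Th17 cells, 1 array of activated CD4+ T cells and 1 polyclonal Th17 culture, so only the sorted cells had replicates. The activated CD4+ and polyclonal samples came from wild type BALB/c mice and were stimulated through CD3 and CD28, so the antigen arm and the transgene could not be told apart. Each array carried probes for 566 mouse and 10 viral microRNAs, all printed here without the prefix mmu-. Detected microRNAs numbered 169, 149, 147 and 147 on sorted replicates 1 to 4, 80 on the array deposited for the antigen culture, 78 for the polyclonal culture and 63 for the CD4 control. The 75th percentile of the signal of probes detected on all arrays was between 804 and 1046 intensity units on the sorted arrays and between 326 and 401 on the 3 unsorted arrays. Values below are log2 signals scaled to that percentile, with a floor at -3.38. Of the 146 microRNAs tested, 54 were detected on all 7 arrays, and 71 lay at the floor on all 4 sorted arrays. The number of arrays limits the precision of every value. No genomic positions are given, because the files name no genome build.

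The deposited records disagreed on which of the 3 unsorted arrays was which. In the authors' table of 197 microRNAs, each of the 4 sorted columns ranked the microRNAs exactly as its own scanner file did (Spearman correlation 1 across microRNAs, 4 of 4 columns). None of the 3 unsorted columns did (0 of 3). The antigen culture column had a Spearman correlation of 1 with the scanner file deposited for the CD4 control and 0.846 with its own. The CD4 column was closest to the antigen culture file, at 0.877, and reached 0.864 with its own. The polyclonal column was also closest to the antigen culture file, at 0.922, and reached 0.746 with its own. The comparison least affected by this is that of the sorted cells with all 3 unsorted arrays at once, and it comes first. It does not depend on which of the 3 names each unsorted scanner file carries. It does assume that all 3 files hold the unsorted samples, which stays open. The files deposited for the antigen and polyclonal cultures matched no column, reaching at best 0.922 and 0.841. Every comparison that names a single unsorted array used the scanner file deposited under that name, and its direction is open to the extent that the name is.

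**Figure D1:**
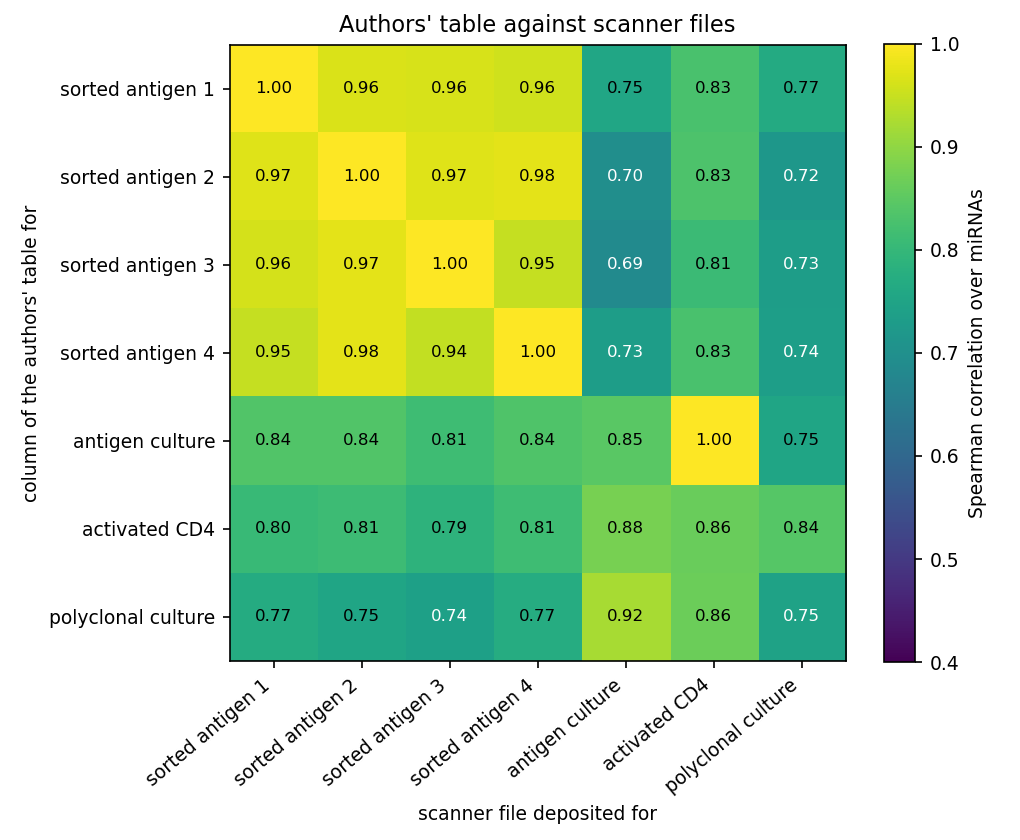
Spearman correlation across microRNAs between each column of the authors' table (vertical axis) and each scanner file (horizontal axis), without units. The 4 sorted columns reach 1 with their own files, and the antigen culture column reaches 1 with the file deposited for the CD4 control.

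In sorted antigen-driven Th17 cells, 9 microRNAs were higher and 7 lower than on each of the 3 unsorted arrays. Ranked by the smallest of the 3 folds, the largest increases were in miR-29b, 4.42- to 6.26-fold (sorted mean 0.49 ± 0.06 SD, n = 4, on the log2 scale), and in miR-106b of a miR-17~92 paralogous cluster, 3.84- to 9.92-fold (-0.01 ± 0.03 SD, n = 4). The activation-induced miR-21, which has been reported to favour Th17 differentiation, rose 2.74- to 4.40-fold (3.99 ± 0.10 SD, n = 4) and let-7i rose 2.54- to 3.24-fold (1.54 ± 0.05 SD, n = 4). The largest decrease by that ranking was in miR-150, which is abundant in resting lymphocytes and lost on activation: it was 4.97- to 13.4-fold lower in the sorted cells (-2.43 ± 0.17 SD, n = 4). MiR-709 was 4.91- to 7.71-fold lower (-0.88 ± 0.46 SD, n = 4) and miR-494 4.08- to 4.63-fold lower (-3.12 ± 0.15 SD, n = 4).

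The other microRNAs raised against all 3 arrays were miR-29a (2.15- to 2.47-fold), miR-20a (2.01- to 9.62-fold), miR-574-5p (1.93- to 4.27-fold), miR-19b (1.69- to 14.1-fold) and miR-15a (1.53- to 2.54-fold). Those lowered were miR-689 (3.11- to 6.87-fold), miR-1224 (2.53- to 3.76-fold), miR-92a (1.68- to 2.28-fold) and miR-26a (1.39- to 1.61-fold). In 11 of the 16, the difference was at least 2-fold against every unsorted array. In a fit limited to the 46 microRNAs above the floor on all 7 arrays, each difference passed the limma threshold on all 3 contrasts. The largest limma adjusted p there was 4.61e-05 for miR-29b, 0.000481 for miR-21, 0.000197 for miR-150 and 0.0488 for miR-1224. In the planned fit of all 146 tested microRNAs, miR-574-5p was not called against the polyclonal array. In that fit miR-689 was not called against the CD4 or polyclonal array, and miR-1224 was called against none. The 4 sorted arrays all lay on the same side of the unsorted ones. The count was taken over the 46 microRNAs above the floor on all 7 arrays, a restriction chosen after the values were seen. Independent lists of the same sizes would share 2.75 higher and 2.02 lower microRNAs. The 3 lists are not independent, since each rests on the same 4 sorted arrays, so that comparison cannot support the count. In 100 simulations with no true difference none was called against all 3 arrays. Those simulations gave the unsorted arrays the mean and spread of the sorted ones and no batch difference. They therefore cannot show whether array or batch variation made the calls. Median absolute log2 differences were 0.06 to 0.15 between sorted arrays and 0.44 to 0.97 between unsorted ones. In the authors' table, 15 of the 16 had the same sign against all 3 unsorted columns, miR-689 being the exception, and 13 passed the test there against all 3 (14 when it was limited to the 46). Without sorted replicate 2 the call against all 3 was lost for miR-574-5p, miR-689 and miR-1224 (13 of the 16 called), without replicate 3 it was lost for the same 3 (13 called), and without replicate 1 for miR-574-5p (15 called). Quantile normalization lost it for miR-574-5p, miR-1224, miR-92a and miR-26a (12 called), and normexp for miR-1224 (15 called). With the mean of all probes it was lost for miR-19b, which no longer had the same sign against all 3 (15 called). All sorted arrays were read in a different batch from all unsorted ones, with another slide, scan and software version, so no value within a batch can be had and sorting and batch cannot be told apart.

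**Figure D2:**
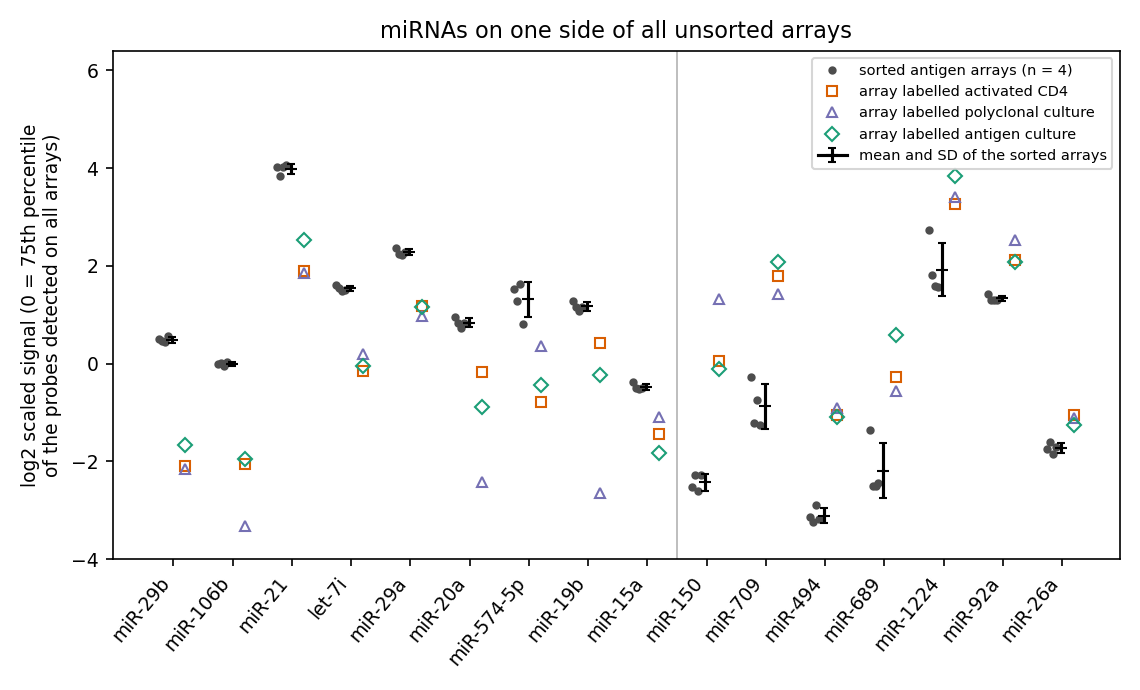
Log2 scaled signal (vertical axis) of the 16 microRNAs (horizontal axis) that differed in the same direction between the sorted arrays and all 3 unsorted arrays. Small dots are the 4 sorted arrays with their mean and SD, and the other symbols are the 3 unsorted arrays. The sorted mean of miR-21 is 3.99 and that of miR-150 is -2.43.

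The families behind these changes moved as follows. Of the 3 members of the miR-29 family, which were fixed among microRNAs high in naive T cells, miR-29a and miR-29b rose against each of the 3 unsorted arrays (2 of 3 over all microRNAs tested and 2 adjusted over the list alone, in every contrast) and miR-29c did not pass. The family's median difference was 1.102 against the CD4 array, 1.31 against the polyclonal array and 1.11 against the antigen culture array, and it stayed above 0 under every alternative scaling and in the authors' table. Its camera p was 0.0348, 0.0451 and 0.0410, and did not pass after adjustment (0.206, 0.271 and 0.246). For the list of microRNAs high in naive cells and lowered on activation, 16 of 18 were tested. Of these, 5 rose and 4 fell against the CD4 array (5 and 5 adjusted over the list alone), 5 rose and 4 fell against the polyclonal array (5 and 4), and 4 rose and 6 fell against the antigen culture array (4 and 6), so it had no common direction. Its members miR-29b and miR-150 moved in opposite directions.

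By their labels, the sorted cells differ from the activated CD4+ control in Th17 polarization, but also in sorting, read-out batch, stimulus and transgene. Against the array deposited for that control, the sorted cells had 24 microRNAs higher and 24 lower. The balance depended on the background step, with 19 higher and 87 lower after normexp and 73 higher and 32 lower without a floor. Beside miR-29b (5.98-fold higher, log2 difference 2.58, SE 0.06, limma adjusted p = 8.38e-05) and miR-21 (4.29-fold higher, log2 difference 2.10, SE 0.11, limma adjusted p = 0.000749), microRNAs of the miR-232724 clusters differed. Of their 5 members 4 were higher and 1 lower (4 and 1 adjusted over the list alone): miR-27b was 3.73-fold and miR-27a 3.42-fold higher, while miR-23a was 2.47-fold lower (log2 difference -1.30, SE 0.05). The microRNAs lower in the sorted cells included miR-150 (5.57-fold, log2 difference -2.48, SE 0.18), miR-146a, a brake on NF-kappaB signalling, which lay at the floor on the 4 sorted arrays and so was at least 4.70-fold lower, and miR-155, which is induced by activation and favours Th17 responses (1.97-fold lower, log2 difference -0.98, SE 0.15, limma adjusted p = 0.0165). All 4 sorted arrays showed each of these directions.

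The remaining named increases in that contrast were miR-574-5p (4.27-fold), miR-106b (4.16-fold), miR-669n (3.93-fold), miR-466c-5p (3.71-fold), let-7i (3.24-fold) and miR-18a (2.36-fold). The remaining decreases were miR-709 (6.32-fold), miR-188-5p (at least 5.53-fold), miR-494 (4.20-fold), miR-714 (at least 3.27-fold), miR-7a (at least 2.43-fold, at the floor in sorted cells) and miR-720 (2.20-fold). Of the 4 sorted arrays, 3 lay at the floor for miR-188-5p and miR-500 and 2 for miR-714 and miR-685, so their folds are lower bounds in every sorted contrast. Detected only in the sorted cells, miR-30e was at least 2.14-fold higher (limma adjusted p = 0.000945), a call that normexp ended (log2 difference 0.20, limma adjusted p = 0.0962). Among the gene lists, the Th17-promoting list had 2 members higher and 1 lower of 10 tested (2 and 1 adjusted over the list alone), the higher ones being miR-21 and miR-301a. Normexp ended the call of miR-301a (log2 difference 0.23, limma adjusted p = 0.0747), and of the list members let-7b and miR-19a. The Th17-restraining list had 2 higher and 4 lower of 9 (2 and 4 adjusted over the list alone), and the list raised on T cell activation 1 higher and 1 lower of 7 (1 and 1). The miR-17~92 clusters had 5 higher and 2 lower of 11 (6 and 2 adjusted over the list alone), with a median of 0.32 that was -0.07 with another background correction (normexp). The let-7 family had 2 higher and 2 lower of 9 (2 and 2), and the B cell and pan-leukocyte list, with miR-150 and miR-146a, none higher and 2 lower of 5 (0 and 3). No list passed camera after adjustment (0 of 18), 4 lists had an unadjusted p under 0.05, none did with an estimated correlation, and fry called 16. Among those 4, the miR-232724 clusters had an adjusted camera p of 0.206, and their median of 0.97 kept its sign under every scaling tried.

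Each of these p values rests on the spread of the 4 sorted arrays alone (3 residual degrees of freedom), the CD4 array being assumed to vary like them. An exact permutation of 4 arrays against 1 cannot go below 0.2. Without sorted replicates 2, 3 and 4 in turn, the limma adjusted p of miR-155 became 0.0634, 0.0693 and 0.0601, and that of miR-709 became 0.0754, 0.0814 and 0.0590. Without replicates 1, 2 and 3 in turn, the limma adjusted p became 0.0821, 0.0865 and 0.0699 for miR-574-5p, 0.127, 0.122 and 0.0749 for miR-669n, and 0.153, 0.149 and 0.0959 for miR-466c-5p, which with the mean of all probes had 0.0532. Of the 48 microRNAs called, 7 lay at the floor on all 4 sorted arrays, where the spread is 0 and the test is too lenient. Among the 52 above the floor on the 5 arrays, 21 were higher and 19 lower. Standard errors depended on the fit too: limited to the 46 microRNAs above the floor on all 7 arrays, that of miR-29b was 0.09 instead of 0.06. The authors' values gave 7 of the 48 the opposite sign, among them miR-188-5p (0.70), and there let-7i, miR-155, miR-23a, miR-27b, miR-466c-5p and miR-669n kept their direction without passing the test.

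The polyclonal Th17 culture differs by its label in the stimulus, receptor cross-linking instead of antigen, and also in transgene, sorting and read-out batch. Against the array deposited for it, 26 microRNAs were higher in the sorted cells and 31 lower (23 and 100 with normexp, 69 and 36 without a floor). In the miR-17~92 clusters, which promote T cell proliferation, 8 of 11 tested members were higher and 1, miR-92a, was lower (8 and 1 adjusted over the list alone), with a median of 1.77 that was 0.00 in the authors' table. MiR-19b was 14.1-fold higher (log2 difference 3.82, SE 0.09, limma adjusted p = 4.57e-05), miR-106b 9.92-fold (3.31, SE 0.04), miR-20a 9.62-fold (3.27, SE 0.10) and miR-20b 3.78-fold (1.92, SE 0.10). This list alone of the 18 passed camera in this contrast (adjusted p = 0.0140), and it did not with an estimated correlation (adjusted p = 0.652). The largest decreases were in miR-685 (at least 16.2-fold, log2 difference -4.02, SE 0.93, limma adjusted p = 0.0407) and miR-150 (13.4-fold, log2 difference -3.74, SE 0.18).

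Other increases were in miR-29b (6.26-fold), miR-24 (4.49-fold), miR-21 (4.40-fold), miR-103 (4.37-fold), miR-27b (3.50-fold) and miR-130b (at least 3.49-fold). MiR-27a and miR-18a, detected on the sorted arrays alone of these 5, were at least 10.9-fold and 4.29-fold higher. Other decreases were in miR-714 (at least 6.73-fold), miR-709 (4.91-fold), miR-494 (4.63-fold), miR-801_v10.1 (3.12-fold), miR-146a (at least 2.78-fold), miR-423-5p (2.65-fold), miR-92a (2.28-fold) and miR-500 (at least 2.08-fold). The miR-232724 clusters had 4 members higher and none lower (4 and 1 adjusted over the list alone), with a median of 1.81 that turned to -0.22 in the authors' table. The Th17-promoting list had 3 higher and none lower of 10 (3 and 0 adjusted over the list alone), among them miR-155, 1.54 higher on the log2 scale. The Th17-restraining list had 4 higher and 2 lower of 9 (4 and 2 adjusted over the list alone), the activation list 2 higher of 7 (2 and 0), the let-7 family 1 higher and 4 lower of 9 (1 and 4), and the B cell and pan-leukocyte list, led by miR-150 and miR-146a, 1 higher and 4 lower of 5 (1 and 4). Normexp ended the calls of miR-142-5p (higher) and miR-342-3p (lower) in that list, and of miR-30e.

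Of the 57 calls, 11 lay at the floor on all 4 sorted arrays. Among the 50 microRNAs above the floor, 19 were higher and 17 lower. The authors' values gave the opposite sign for 17 of the 57, among them miR-24, miR-103, miR-20b, miR-27b, miR-130b and miR-500, and there miR-685 and miR-423-5p kept their direction without passing the test. Without sorted replicates 2, 3 and 4 in turn, the limma adjusted p of miR-685 became 0.112, 0.105 and 0.0900, and that of miR-709 became 0.0808, 0.0933 and 0.0690. Without replicates 1, 2 and 4 in turn, it became 0.0699, 0.0661 and 0.0629 for miR-500 (0.107 with the software's sums), and without replicates 1, 3 and 4 it became 0.0721, 0.0835 and 0.0626 for miR-801_v10.1.

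Against the array deposited for the unsorted antigen-driven culture, the comparison closest to the effect of sorting, 21 microRNAs were higher in the sorted cells and 30 lower (16 and 88 with normexp, 74 and 36 without a floor). The increases again included miR-29b (4.42-fold, log2 difference 2.15, SE 0.06, limma adjusted p = 0.000113), miR-106b (3.84-fold), miR-20a (3.33-fold), let-7i (3.01-fold), miR-21 (2.74-fold), miR-19b (2.63-fold), miR-15a (2.54-fold) and miR-27a (2.51-fold). MiR-18a, which lay at the floor in the unsorted culture, was at least 4.29-fold higher. Lower in the sorted cells were miR-714 (log2 difference -3.71, SE 0.17, a lower bound on the size), miR-709 (7.71-fold), miR-689 (6.87-fold), miR-801_v10.1 (4.98-fold), miR-150 (4.97-fold, log2 difference -2.31, SE 0.18) and miR-494 (4.08-fold). MiR-23a was 3.24-fold and miR-188-5p at least 3.12-fold lower, and miR-690 at least 3.39-fold lower.

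MiR-721, which is known from work on antigen-driven Th17 cells that may rest on these same samples, was bright on the array deposited for the antigen culture (-0.84) and below the floor on the 4 sorted arrays, so it was at least 5.78-fold lower there. It was detected dimly on all 4 sorted arrays and not on the arrays deposited for the CD4 control or the polyclonal culture. In the authors' log2 table it stood at 2.66 in the antigen culture and at 5.01, 2.69, 2.88 and 4.27 in sorted replicates 1 to 4, while the CD4 and polyclonal columns listed it at 0. With those values raised to a common floor, the sorted mean was 0.17 above the antigen culture (log2), and only replicate 1 lay above the floor.

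For the miR-17~92 clusters 6 members were higher and 2 lower of 11 in this contrast. For the let-7 family 2 were higher and none lower of 9, for the miR-232724 clusters 1 higher and 2 lower of 5, and for the B cell and pan-leukocyte list 2 higher and 2 lower of 5. For the Th17-promoting list 2 were higher and 1 lower of 10, for the Th17-restraining list 3 higher and 3 lower of 9 and for the activation list 1 higher of 7. The counts adjusted over the list alone were the same for each of these. The lower member of the Th17-promoting list was miR-721, which is not counted as independent evidence because its source may rest on these samples. Of its higher members, miR-301a, not detected on any unsorted array, lost the call with normexp (log2 difference 0.19, limma adjusted p = 0.131). So did the list members miR-142-5p, miR-20b and miR-30e, and miR-26b changed sign. No list passed camera after adjustment (0 of 18), 3 had an unadjusted p under 0.05, none with an estimated correlation, and fry called 12. Of the 51 calls 12 lay at the floor on all sorted arrays, and 9 had the opposite sign in the authors' table, where miR-188-5p, miR-690 and miR-801_v10.1 kept their direction without passing the test. With the software's sums miR-188-5p did not pass either (limma adjusted p = 0.0505). Among the 55 microRNAs above the floor, 20 were higher and 15 lower. Without sorted replicates 2 and 3 in turn, the limma adjusted p of miR-709 became 0.0514 and 0.0615. Without replicates 2, 3 and 4 that of miR-689 became 0.106, 0.104 and 0.0932, and without replicates 1, 2 and 3 that of miR-574-5p, 3.36-fold higher with all 4, became 0.115, 0.113 and 0.0881.

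The remaining comparisons set 1 array against 1 within the batch of the unsorted arrays. They have no replicates, so the main analysis gives sizes and no test for them. Between the arrays deposited for the antigen-driven culture and for the activated CD4+ cells, the antigen culture was higher in the miR-232724 clusters, with a median difference of 1.04 that was -0.17 in the authors' table. MiR-23b was 4.62-fold (log2 difference 2.21, SE between spots 0.02), miR-27b 4.30-fold (2.10) and miR-24 2.06-fold (1.04) higher. Their median lay at percentile 99.7 of 10000 random lists matched on signal, unadjusted over the lists. Whether probes of these clusters bind one another's microRNAs could not be tested, so the members may not be separate measurements. MiR-146a was 4.11-fold lower (-2.04) and miR-142-5p 2.18-fold lower (-1.12), against 1.22 and -0.11 in the authors' table. The B cell and pan-leukocyte list stood at percentile 0.605 with a median of -0.92, against -0.26 there. In all, 11 microRNAs were at least 2-fold higher and 6 at least 2-fold lower of the 83 detected on either array. Others higher were miR-714 (4.02-fold), miR-690 (3.03-fold), miR-801_v10.1 (2.91-fold) and miR-685 (2.60-fold), and others lower were miR-720 (2.12-fold), miR-26b (2.07-fold) and miR-20b (2.06-fold). MiR-721, miR-483, miR-706 and miR-361 were detected on the antigen culture array alone and at least 5.78-, 4.53-, 2.64- and 2.24-fold higher. MiR-7a, detected on the CD4 array alone of this pair, was at least 2.43-fold lower.

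Between the arrays deposited for the polyclonal culture and the activated CD4+ cells, the polyclonal culture was lower in the miR-17~92 clusters, with a median of -0.86 that was 0.52 in the authors' table. MiR-19b was 8.34-fold (log2 difference -3.06), miR-20b 5.45-fold, miR-20a 4.79-fold and miR-106b 2.39-fold lower, and 5 of 11 members were at least 2-fold lower and none higher. The median lay at percentile 0.45 of random lists. MiR-155 was 5.76-fold lower (-2.53). The list fixed for the Sfmbt2 cluster of chromosome 2, a large repeat-derived group, was higher in 6 of 7 tested members, with a median of 1.14 at percentile 99.1 that turned to -1.76 in the authors' table. Of these, miR-574-5p (2.21-fold higher) is on chromosome 5 in the gene annotation. Without it 5 of 6 were higher, with a median of 1.14 at percentile 97.52, against -2.26 in the authors' table. Whether probes of this list bind one another's microRNAs could not be tested, so its members may not be separate measurements. On the sorted arrays, miR-466c-5p, miR-466h, miR-669a, miR-669b and miR-574-5p were all lowest on replicate 4. MiR-466c-5p was 2.21-fold and miR-669a 2.20-fold higher. MiR-685 was 17.1-fold (4.09) and miR-150 2.40-fold higher, but at -1.05 and -0.52 in the authors' table. In all, 17 microRNAs were at least 2-fold higher and 13 at least 2-fold lower of 86 detected on either array. MiR-468 (3.31-fold), miR-669n (2.28-fold), miR-714 (2.06-fold) and let-7b (2.03-fold) were also higher, and miR-188-5p (4.59-fold), miR-103 (2.52-fold), miR-24 (2.29-fold) and miR-23a (2.21-fold) lower. The median of the miR-232724 clusters was -1.14, at percentile 7.28, and 0.82 in the authors' table.

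Between the arrays deposited for the antigen-driven and the polyclonal culture, all 5 members of the miR-232724 clusters were at least 2-fold higher in the antigen-driven one, with a median of 2.07 at percentile 99.5 that turned to -0.99 in the authors' table. MiR-24 was 4.72-fold, miR-23b 4.20-fold, miR-27b 4.03-fold and miR-23a 2.90-fold higher, and miR-27a, detected on that array alone, at least 4.35-fold higher. MiR-19b was 5.36-fold (log2 difference 2.42), miR-93 at least 4.62-fold, miR-103 3.87-fold, miR-155 3.58-fold, miR-20a 2.89-fold and miR-20b 2.64-fold higher. Lower in the antigen-driven culture were miR-685 (6.58-fold, -2.72), miR-150 (2.69-fold), let-7g (2.54-fold), miR-146a (2.44-fold) and miR-669a (2.37-fold). The let-7 family had 2 of 9 members at least 2-fold lower and none higher (median -0.84, percentile 0.99, against a median of -0.06 in the authors' table). The B cell and pan-leukocyte list stood at a median of -1.22 and percentile 1.09, against 0.24 in the authors' table, and the Sfmbt2 list at -1.14 and percentile 2.04, against 1.09 there (without miR-574-5p -1.19 and 1.75, against 0.54). In all, 20 microRNAs were at least 2-fold higher and 16 at least 2-fold lower of 95 detected on either array.

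The Th17-promoting list stood at percentiles 46.8, 49.1 and 92 in these 3 comparisons, taken in the order given. Its medians were 0, 0 and 0.049, and 5, 3 and 5 of its 10 tested members were detected on either array. Members at the floor on both arrays differ by 0, so these percentiles cannot show whether the list shifted. The directions depended on the source of the values: of the microRNAs at least 2-fold apart, 9 of 17, 24 of 30 and 20 of 36 had the opposite sign in the authors' table. Across the microRNAs detected on both arrays, which are not independent replicates, the Pearson correlation between the differences from the scanner files and from the authors' table was -0.43, -0.49 and -0.21. For the sorted contrasts against the CD4, polyclonal and antigen culture arrays it was 0.74, 0.48 and 0.70.

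**Figure D3:**
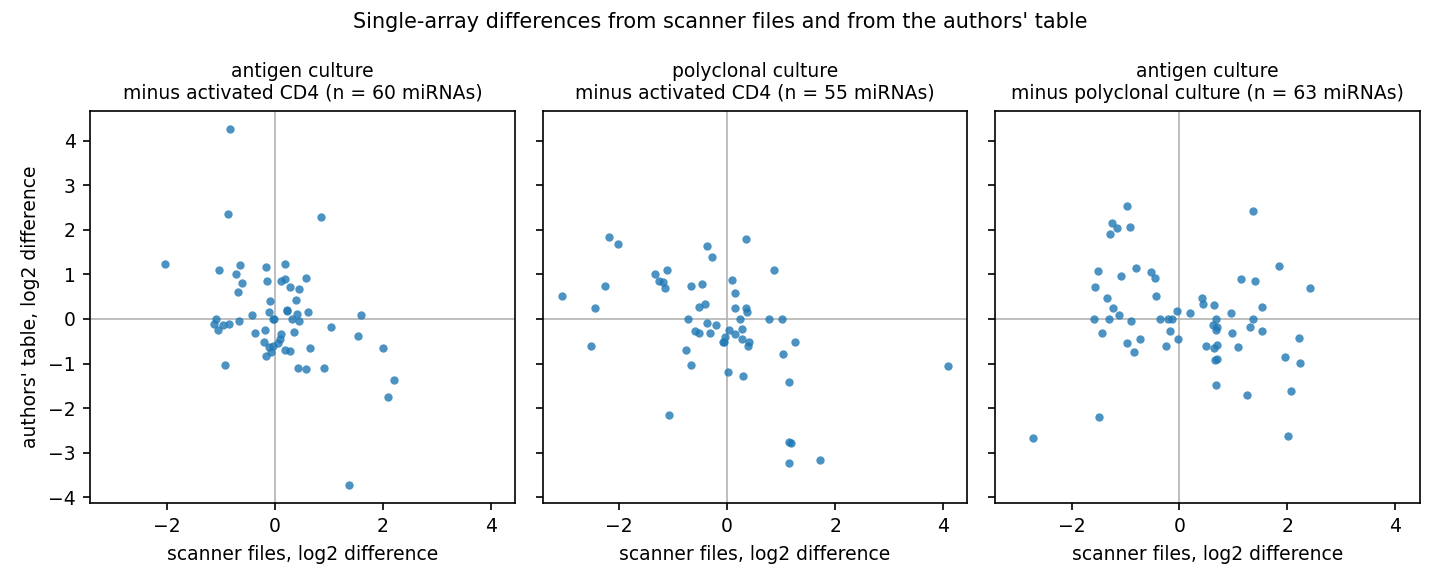
Log2 differences between single unsorted arrays, from the scanner files (horizontal axis) and from the authors' table (vertical axis), with 1 dot per microRNA detected on both arrays, for 60, 55 and 63 microRNAs. The Pearson correlations across microRNAs are -0.43, -0.49 and -0.21.

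No microRNA was at least 2-fold above the CD4 array on all 6 Th17 arrays, and 1 was at least 2-fold below it, miR-7a, which lay at the floor on the sorted arrays. Simulations without any Th17 effect, with the spread of the sorted arrays on every array, gave means of 0.024 and 0.136. An exact permutation of 6 arrays against 1 cannot go below 0.143. In the authors' table miR-18a was higher on all 6, and miR-139-5p and miR-685 were lower. Between the antigen-driven and the polyclonal culture, each set against the CD4 array, 2 of the 54 microRNAs detected on all arrays were at least 2-fold higher in both and 1 lower in both, and 1 moved in opposite directions. Independent lists of the same sizes would share 1.17 higher and 1.02 lower, but these lists share the CD4 array and so are not independent. Simulations in which the shared CD4 array alone linked the contrasts gave 0.226 higher in both and 0.269 lower in both. The Pearson correlation of both sets of differences across microRNAs was 0.37, against 0.47 in those simulations, and their covariance was 0.38, against 0.0579. The 1 opposite call compares with 0.037 simulated. A simulated covariance that small means that the CD4 array was drawn with little spread. Median absolute log2 differences were 0.44 to 0.97 between unsorted arrays and 0.06 to 0.15 between sorted ones. These simulations therefore cannot show whether the cultures share changes beyond the CD4 array.

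Of 22 markers of myeloid, erythroid, endothelial, stromal or epithelial cells on the array, none was detected on 2 or more of the unsorted arrays. Those arrays detected only 63 to 80 of all 576 microRNAs. All 5 members of the B cell and pan-leukocyte list were detected on all 7 arrays. MiR-223, a myeloid and platelet microRNA, was detected on the array deposited for the CD4 control and on all 4 sorted arrays. No erythroid, stromal or epithelial marker was among the microRNAs tested, and the muscle and liver list had 1 tested member, miR-206, detected on all 4 sorted and 1 of the unsorted arrays. Of the neural list, miR-7a was detected on all 4 sorted and 2 unsorted arrays and miR-128 on the 4 sorted arrays. Smaller families had few calls against the CD4, polyclonal and antigen culture arrays in turn. The miR-15/16 family had 1, 2 and 1 of 4 members higher and 1, 0 and 1 lower, and the miR-30 family 1, 1 and 1 of 5 higher and 1, 0 and 3 lower. The miR-181 family had none of 4 higher and 0, 0 and 1 lower. The Sfmbt2 list had 2, 0 and 1 of 7 higher and 0, 1 and 0 lower (without miR-574-5p, 1, 0 and 0 of 6 higher), and the Dlk1-Dio3 list had miR-494 lower each time. Adjusted over the list alone, the counts of these families were the same, except 1 and 0 higher for the Sfmbt2 list against the CD4 and antigen culture arrays. The miR-99b and miR-183 clusters, with 2 tested members each, had no call. Some calls in these counts paired small log2 differences with very small limma adjusted p, as calls with almost no spread do. They were miR-181a (-0.61, 1.40e-12) and miR-30b (-0.84, 8.13e-10) against the antigen culture array. Against the CD4 array miR-30b was another (-0.93, 6.77e-10), and against the polyclonal array miR-297c (-0.47, 3.00e-06). Near or at the floor, miR-223 was lower against the CD4 array (-0.64, log2), and so was the neural list's miR-7a, 1 of its 2 tested members, while miR-206, miR-7a and the viral mghv-miR-M1-6, 1 of 3 tested viral microRNAs, were lower against the polyclonal array, all calls where the sorted arrays have almost no spread.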

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

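The identity tests, the marker test and the read-out batch test in this part were chosen after the result was seen, and the background re-centring test was written down before its result was seen but planned after the arrays had been examined.

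Among 48 measures of the 4 sorted arrays, 8 had 1 array far from the other 3 by Dixon's criterion, where chance flags about 1 in 20, or 2.4 here. Replicate 1 had 169 detected microRNAs against 147 to 149 on the others. Replicate 3 had a 75th percentile of 804 intensity units against 1018 to 1046. MiR-801_v10.1 was at -3.27 on replicate 2 against -2.71 to -2.61 on the log2 scale. MiR-155 was at 0.62 on replicate 1 against 0.30 to 0.35. MiR-423-5p was at -3.17 on replicate 1 against -3.35 to -3.33. Let-7g was at 1.01 on replicate 3 against 1.16 to 1.19. MiR-92a was at 1.42 on replicate 1 against 1.30 to 1.31. MiR-689 was at -1.35 on replicate 1 against -2.50 to -2.44.

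The columns of the authors' table for the 3 unsorted samples ranked unlike their own scanner files. Re-ranking by the authors' normalization was argued against by the 4 sorted columns of the same table, whose lowest Spearman correlation with their own files was 1. A swap of the 3 scanner files among the 3 samples was argued against too, since the best correlation of the CD4 and polyclonal columns with any of the 7 files was 0.922. A mislabelled sample may account for part of it: the antigen culture column had a correlation of 1 with the scanner file deposited for the CD4 control, and the slide position in the antigen culture's label is the position in that file. The slide positions in the labels of the CD4 and polyclonal samples were found in none of the unsorted scanner files. Whether the file or the column carries the wrong name stays open, as does the source of the CD4 and polyclonal columns.

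Sorted cells differed in the same direction from all 3 unsorted arrays in 16 microRNAs above the floor, among them miR-29b, miR-21 and miR-150. An over-subtracted background on the unsorted arrays could push dim microRNAs down there; with the background re-centred, 24 microRNAs were called against all 3 where 23 had been (22 shared), and 17 against 16 above the floor, which argues against it as the whole cause. Myeloid, erythroid, endothelial, stromal or epithelial cells in the cultures were argued against only weakly. Of their marker microRNAs 0 of 22 were detected on 2 or more unsorted arrays, but those arrays detected only 63 to 80 of 576 microRNAs. Small shares stay open, and miR-223 was on the CD4 array and all sorted arrays. B cells and other leukocytes stay open, since all 5 members of their list, which T cells also express, were detected on all 7 arrays; in the sorted cells 4 of them were lower than on the polyclonal array and miR-150 and miR-146a (at the floor) lower than on each unsorted array, while miR-142-5p was higher than on the polyclonal array, and it and miR-142-3p than on the antigen culture array (normexp ended both calls of miR-142-5p). Read-out batch and sorting cannot be told apart, because 0 unsorted arrays were read in the batch of the sorted ones, and a biological difference between sorted Th17 cells and whole cultures was not tested and stays open.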

How the results depend on the processing

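The re-centred background, the normexp correction on the median signal, the restriction to microRNAs above the floor, the count against all 3 unsorted arrays and the Sfmbt2 list without miR-574-5p were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because no label pairs a sorted array with an unsorted one, and no comparison has 3 or more arrays in both groups. Scaling by the 75th percentile over all probes was not run, since that percentile is negative on the 3 unsorted arrays. Signal over background limits all counts: the unsorted arrays detected 63 to 80 microRNAs and the sorted ones 147 to 169.

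Main counts were 17, 30 and 36 microRNAs at least 2-fold apart (antigen culture against CD4, polyclonal against CD4, antigen culture against polyclonal), 48, 57 and 51 called in the sorted contrasts (against CD4, polyclonal, antigen culture), 1 in the same direction on all 6 Th17 arrays and 16 against all 3 unsorted arrays. The following left a factor of 1.5, and unless stated the cause was not tested. Normexp gave 9, 9 and 13 apart, 106, 123 and 104 called (19, 23 and 16 of them higher) and 0 on all 6; its offset is divided by larger factors on the sorted arrays, which lowers dim microRNAs there. No floor gave 29, 50 and 57 apart, 105, 105 and 110 called (73, 69 and 74 higher) and 4 on all 6. The software's sums gave 28 and 47 in the CD4 pairs and the mean of probes 19 for polyclonal against CD4. The authors' values gave 26 for antigen culture against CD4. A 1.5-fold threshold gave 38, 46, 60 and, on all 6, 7, and the spread of the sorted arrays gave 40 and 55 for antigen culture against CD4 and polyclonal. Asking for at least 2-fold gave 23, 30 and 30 called, and microRNAs above the floor 36 against polyclonal, both being stricter by construction. The 5 antigen arrays as 1 group gave 9 against CD4 and 24 against polyclonal. With a batch block that grouping rests on the single antigen culture array, so its 40 (22 higher, 18 lower) and 55 (34 higher, 21 lower) repeat the counts of that array with the spread of the sorted arrays. On all 6 arrays, quantile normalization and the authors' values gave 3 each, and the mean of probes, detection on all 7 arrays and re-centring gave 0 each. Fry called 16, 17 and 12 lists, camera with an estimated correlation 0 against polyclonal where the preset gave 1, and quantile normalization left 2 of 4 extreme lists for antigen culture against polyclonal. The count against all 3 unsorted arrays ranged from 11 to 23. The 23 came from all tested microRNAs (15 higher, 8 lower), where simulations that drew the unsorted arrays alone gave a mean of 8.69 lower by chance, so the lower calls at the floor are not reliable. Without 1 sorted array the counts were 36 to 43, 49 to 54 and 44 to 51 in the sorted contrasts, 1 to 1 on all 6 and 13 to 20 against all 3.

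The share higher moved by over 10 points in some settings, for example to 11 higher and 3 lower with re-centring for antigen culture against CD4, and 10 higher and 4 lower with quantile normalization against all 3. The median difference moved by 0.1 or more (log2) with normexp, by -0.20, -0.44 and -0.30 in the sorted contrasts; with quantile normalization by -0.20 and -0.19 in the antigen culture pairs and 0.10 for sorted against polyclonal; with the software's sums by 0.24 for antigen culture against polyclonal, 0.10 for antigen culture against CD4 and 0.14 for sorted against CD4; with no floor by -0.20 for sorted against polyclonal; and with the authors' values by -0.19 for antigen culture against polyclonal.

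Of the values of named microRNAs, 51 reversed, all with the authors' values, where 58 others stayed; a wrong name on 1 or more unsorted files could reverse them, and the cause was not tested. With every other alternative 0 reversed. Reversed log2 differences for antigen culture against CD4 were miR-23b -1.38, miR-27b -1.76, miR-714 -0.66, miR-801_v10.1 -0.37, miR-685 -3.73, miR-24 -0.17, miR-361 -1.28, miR-146a 1.22 and miR-20b 1.103. For polyclonal against CD4 they were miR-685 -1.05, miR-468 -3.16, miR-150 -0.52, miR-669n -2.79, miR-574-5p -1.42, miR-466c-5p -3.24, miR-669a -2.77, miR-714 -0.79, miR-466h -1.76, miR-672 -1.93, miR-669b -2.76, miR-19b 0.52, miR-20b 0.25, miR-20a 0.75, miR-188-5p 1.845, miR-93 1.67, miR-103 1.002, miR-106b 0.86, miR-24 0.82, miR-23a 0.70 and miR-27a 0.88. For antigen culture against polyclonal they were miR-24 -0.99, miR-93 -0.44, miR-23b -1.625, miR-27b -2.63, miR-103 -0.85, miR-23a -0.28, miR-27a -0.19, miR-361 -1.73, miR-672 0.72, miR-669b 1.09, let-7g 0.46, miR-146a 1.92 and miR-669a 2.14. In the sorted contrasts they were miR-188-5p 0.70 against CD4, miR-24 -0.18, miR-103 -0.43, miR-20b -0.034, miR-27b -0.22, miR-130b -0.079 and miR-500 1.42 against polyclonal, and miR-721 0.17 against antigen culture.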

Other observations

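The test of neighbouring microRNA genes in this part was chosen after the differences had been seen.

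Against the polyclonal array, let-7i was 2.54-fold higher in the sorted cells while 4 of the 9 members of the let-7 family were lower. Against the antigen culture array 2 were higher and none lower. MiR-92a was 1.68- to 2.28-fold lower in the sorted cells than on each unsorted array, while miR-19b and miR-20a, which are processed from the same primary transcript, were higher on the same arrays. MiR-26a, which restrains proliferation in several cell types, was 1.39- to 1.61-fold lower. With quantile normalization miR-92a and miR-26a were no longer called against all 3, and with the mean of all probes miR-19b lost both the call and its common sign.

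A hypothesis was that differences between arrays follow shared precursors, so that neighbouring microRNA genes of different seed families differ alike. In 10 pairs of genes within 10000 bases, built from 11 microRNAs, the mean absolute difference between neighbours was 0.61 (log2) for the antigen culture against the polyclonal array and 1.40 in permuted pairs (permutation p = 0.00490, adjusted p = 0.0294 over 6 contrasts). In the other 5 contrasts the permutation p was 0.0561 to 0.542. With the authors' values the permutation p of that contrast was 0.0480, and that of polyclonal against CD4 was 0.000600, where the scanner files gave 0.0561. Of the 10 pairs, 6 lie within the miR-232724 clusters, whose differences prompted the hypothesis, so this test says little. The 4 other pairs, also chosen after the values were seen, gave a mean absolute difference of 1.06 against 1.29 in permuted pairs (permutation p = 0.341). For antigen culture against CD4 their permutation p was 0.00910 and in the other 4 contrasts 0.206 to 0.536, so the hypothesis stays open.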
